A study of Oryza sativa Japonica Group with 38 samples.

How the data were processed

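Rice (Oryza sativa, japonica) RNA was sequenced in 38 libraries from 9 conditions. Per the labels, seedlings were grown for 2 weeks with 12 h of light at 28 °C and 12 h of dark at 22 °C, and were left untreated or exposed to cold (4 °C), drought (air drying), heat (50 °C), high light (50000 lux) or high salt (300 mM NaCl). Leaves, panicles and roots without treatment were the other 3 conditions, and their labels also give seedlings of 2 weeks, panicles included. From each condition came a poly(A)+, a poly(A)-, a nuclear and a small RNA library. The labels give the poly(A)+, poly(A)- and small RNA as whole cell RNA, and the nuclear RNA as nuclear total RNA. Drought had 2 libraries each of the poly(A)+ and poly(A)- kinds, and every other group was a single library. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was depleted in repeated rounds with a plant kit, and oligo(dT) beads then parted poly(A)+ from poly(A)- RNA. Libraries were strand-specific by the dUTP method.

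The authors deposited a list of annotated long noncoding RNAs (lncRNAs, transcripts without coding capacity) and a list of assembled loci with XLOC identifiers. Per the file headers, each list gives coordinates, exons, the authors' poly(A) and location classes and 36 columns of FPKM, fragments scaled to exon length and to the reads of the library. The submitters' processing notes name TopHat2, DESeq2 and the build IRGSP-1.0, with no role or version. The read counter, the rules for the classes and the handling of reads that map to several places or to both strands are not given in the sources used here. Coordinates are given as deposited, and lengths are the sum over exons of end minus start. No annotation of this build was used here, and none of the identifiers had a match in the RefSeq table of assembly ASM3414082v1, so loci carry no gene names and their position against protein-coding genes was not analysed here. Planned tests of neighbouring genes were therefore not run, and the files held no comparison columns of the authors.

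Depth was recovered from the deposited FPKM values. In each column, FPKM times exon length was a whole multiple of 1 step for 100% of the 99470 values of single-exon genes checked, up to 200 reads and within 0.05 reads. The step gives the value of 1 read and the depth of the library. Exact 95% Poisson intervals were computed on the recovered reads, and a locus listed at 0 is given a limit of 3 reads, which is below the upper end of the two-sided interval. Intervals and limits cover counting error only. The drought columns also held whole reads of a single depth, so they were not averages of 2 FPKM columns. Which drought library or pool they came from is not given in the sources used here.

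The step also tells libraries apart. In 32 of the 36 columns it was equal in both lists, with a largest relative difference of 3.7e-07. In the other 4 columns it differed by at least 5.82%, and the 4 steps of one list recurred in the other list under other headings. These columns (poly(A)+ of leaves, and poly(A)+, poly(A)- and nuclear RNA of panicles) were left out of the main comparisons and entered only alternatives, the rule for the authors' classes and tissue counts given under each reading of the headings. The authors' classes were taken as deposited and may rest on these columns too. The design, the rule for named loci and most alternatives were fixed before the data were examined, and that design had 9 conditions for the fraction tests. The tests here had 7 conditions (6 of seedlings, and roots) where poly(A)+ RNA took part and 8 (with leaves) for nuclear against poly(A)- RNA.

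Fractions were compared with limma on log2(FPKM + 1), with condition as a block and a trended prior for the spread. Genes of at least 1 FPKM in at least 3 of the tested libraries entered. The threshold was a Benjamini-Hochberg adjusted p of 0.05 and a difference of at least 2-fold. A fold change on this scale understates the change of low genes. The prior had 187, 23.4 and 137 degrees of freedom beside 6, 6 and 7 residual ones for poly(A)- against poly(A)+, nuclear against poly(A)+ and nuclear against poly(A)- RNA, so small p-values rest mostly on spread shared between genes. Nothing in the labels says that libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. On simulated data with 200 changed genes per comparison, differences of 1.5 on the log2 scale were called in 68%, 83% and 92% of cases and differences of 2.5 in 97%, 96% and 100%. There were 6, 5 and 3 false calls among the unchanged genes of 2859, 2786 and 959 simulated. The simulated fractions had no shift between whole libraries, so these false calls do not cover such shifts.

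Stressed against untreated seedlings, and tissues against leaves, had 1 column per group. They were compared by size without a test: at least 2-fold on log2(FPKM + 1) and at least 1 FPKM in one of the columns. A locus was named over fractions where all compared long RNA fractions passed in the same direction. The overlap of independent lists was computed among the loci of at least 1 FPKM in every compared fraction. Fractions of 1 condition are not replicates and may share RNA, so a larger overlap is no separate support. On simulated read counts with no spread but counting error, the rule recovered 98%, 96% and 93% of 4-fold changes in poly(A)+, poly(A)- and nuclear libraries, and no unchanged locus passed among the 7231 simulated. The lists were compared by two-sided permutation tests of the difference in medians across transcripts (100000 resamples, 6 measures in the family), and class shares by Fisher's exact test, both with Benjamini-Hochberg adjustment. In 100 simulated comparisons of 500 values per list, a shift of 0.2 SD passed 0.05 in 74% and no shift in 7%.

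Named loci followed a rule fixed at the same time: per fraction comparison, the 10 smallest adjusted p-values in each direction with the same sign in every condition, and per stress or tissue up to 5 higher and 5 lower loci of largest mean difference among those past the rule in all fractions. Because no names go with the identifiers, only the leading ones are printed. Alternatives were other pseudocounts, filters, fold limits, median centring, left-out conditions and other controls, and, chosen after seeing the data, 9 conditions under 3 readings of the disputed headings a comparison with RAP loci alone, and seedlings in place of leaves for roots over both fractions. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.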

Results

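The study asked which rice lncRNAs respond to stress, and in which RNA fraction they are found. The undisputed long RNA libraries held between 49.2 and 105 M reads each (M, reads in units of 1e6), and the small RNA libraries between 39.7 and 85.8 M. The listed lncRNAs took between 0.451% and 3.39% of the reads of a long RNA library. Every group had a single column in the files, so its values carry counting intervals and no replicate error. Whether the drought columns of poly(A)+ and poly(A)- RNA hold 1 of 2 libraries or a pool is not given in the sources used here.

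The annotated list held 3722 genes, and the XLOC list 3509. The annotated list joined 1873 genes with RAP locus identifiers, with a median length of 631 nt, and 1849 genes with EPlOSAG identifiers, all of 1 exon, with a median of 271 nt. RAP and XLOC loci were widely detected in long RNA: 61.6% and 81.4% of them reached 1 FPKM in at least 1 of the 23 undisputed libraries. EPlOSAG loci were mostly silent there, with 42 genes (2.27%) at 1 FPKM and 1355 (73.3%) listed at 0 in all 23. In small RNA, however, 955 EPlOSAG genes (51.6%) reached 1 FPKM, against 82 RAP genes (4.38%) and 327 XLOC genes (9.32%). Of the EPlOSAG genes, 1042 had a twin on the other strand. In small RNA, such partners had equal reads in 5 of 329 pair values of at least 40 reads, and reads within counting error of equal in 140. How reads were split between strands and copies is not given in the sources used here, so values of single EPlOSAG loci are uncertain.

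XLOC transcripts were longer and more abundant in long RNA than annotated ones and lower in small RNA. Median length was 559 nt (interquartile range 360 to 890) for 3610 XLOC transcripts and 285 nt (260 to 681) for 3726 annotated transcripts. The median of the mean log2(FPKM + 1) was 0.40 against 0.01 in long RNA, and 0.01 against 0.14 in small RNA. Each of these differences had an adjusted permutation p of 1e-05, the smallest the resamples can give. Exon number had a median of 1 in both lists, as 91.8% of XLOC and 75.4% of annotated genes had a single exon, so medians could not part them. Its mean was 1.17 ± 0.692 against 1.75 ± 1.94 (SD; adjusted permutation p = 1e-05). The median log2 difference of nuclear from poly(A)+ RNA was -1.54 for 1942 XLOC and -1.78 for 987 annotated transcripts (adjusted permutation p = 1e-05), and that of poly(A)- from poly(A)+ RNA was -1.47 and -1.54 (adjusted permutation p = 0.148). Against the RAP transcripts alone, XLOC transcripts were 72 nt shorter in the median, and the differences in level missed the threshold in long RNA (adjusted permutation p = 0.182) and in small RNA (adjusted permutation p = 1). Matched on level in long RNA, length differed by -9 nt (adjusted permutation p = 0.63), and the small RNA level and the nuclear to poly(A)+ difference also missed the threshold (adjusted permutation p = 0.241 for both). Transcripts are not independent replicates, and the lists were made by the authors' own filters. If XLOC loci were assembled from these long RNA reads, their detection and level there would follow partly from that selection.

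The authors' classes put 2294 of 3509 XLOC genes (65.4%) and 1592 of 3722 annotated genes (42.8%) in the poly(A)+ class. The poly(A)- class held 252 XLOC genes (7.18%) and 137 annotated genes (3.68%), and the class of both kinds 934 (26.6%) and 492 (13.2%). The remaining annotated genes, 1501 (40.3%), were called low, against 29 XLOC genes (0.826%). By location, 2617 XLOC genes (74.6%) and 1620 annotated genes (43.5%) were called cytosolic, and 458 (13.1%) and 203 (5.45%) nuclear. All of these shares differed between the lists (Fisher's exact test, two-sided, largest adjusted p = 3.6e-11). They are shares of all genes, and by location 46.9% of annotated and 1.71% of XLOC genes were called low. Of the 2221 annotated and 3480 XLOC genes with another poly(A) class than low, 1592 and 2294 were poly(A)+. That share is larger for annotated genes, as is the cytosolic share once low genes are left out. These shares without low genes were not tested. Among genes of at least 300 nt the poly(A)+ share was 65.9% for XLOC and 70.9% for annotated genes, the opposite order, and the cytosolic share was 76% and 73.5% (Fisher's exact test, adjusted p = 0.057). The XLOC classes may also rest on the disputed columns. A 4-fold rule on the highest values gave another poly(A) class for 32 of 3480 XLOC genes with columns as headed. Under the annotated headings it did so for 718.

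Most lncRNAs were lower in poly(A)- than in poly(A)+ RNA, and a small set, mostly XLOC loci, was higher. Of 2859 genes tested over 7 conditions, 2131 were lower in poly(A)- RNA and 120 higher. The lower genes comprised 745 RAP, 14 EPlOSAG and 1372 XLOC loci, and the higher ones 2, 13 and 105. Of the higher EPlOSAG loci, EPlOSAG00000046976, EPlOSAG00000046987, EPlOSAG00000046998 and EPlOSAG00000047009 were all of 526 nt, with poly(A)- means of 15.2 to 26.7 FPKM. Whether they share reads was not measured, so they may not be separate results. The same sign in all 7 conditions was seen for 1836 of the lower and 97 of the higher genes. Among the higher genes, EPlOSAG00000045065, a 240 nt locus on chromosome 1 (24615787 to 24616027, + strand), averaged 232 ± 296 FPKM in poly(A)- and 11.5 ± 25.7 FPKM in poly(A)+ RNA (SD, n = 7 conditions). Its log2 difference was 5.26 ± 0.49 (SE, limma adjusted p = 1.96e-18). XLOC_053321 on chromosome 4 (16289096 to 16289458, + strand) averaged 117 ± 120 against 3.06 ± 3.99 FPKM, a log2 difference of 4.73 ± 0.46 (limma adjusted p = 2.04e-17). Among the lower genes, XLOC_064094 on chromosome 5 (185871 to 186076, - strand) averaged 0.833 ± 1.05 in poly(A)- and 68.1 ± 61.4 FPKM in poly(A)+ RNA (limma adjusted p = 8.11e-20). OS09G0568266 on chromosome 9 (22692731 to 22694212, - strand) averaged 0.682 ± 0.28 against 41.9 ± 25.6 FPKM (limma adjusted p = 1.13e-17).

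The size of this difference was not the same in all conditions. The median log2 difference was -2.16 in untreated seedlings, -1.92 in heat, -1.87 in roots, -1.71 in cold and -1.56 in high light, but -1.10 in drought and -0.43 in high salt. The fit itself had a median of -1.51. Relative to the median of each library, 472 genes were lower in poly(A)- RNA and 245 higher, and all 472 and 120 of the 245 were also called without centring.

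**Figure D1:**
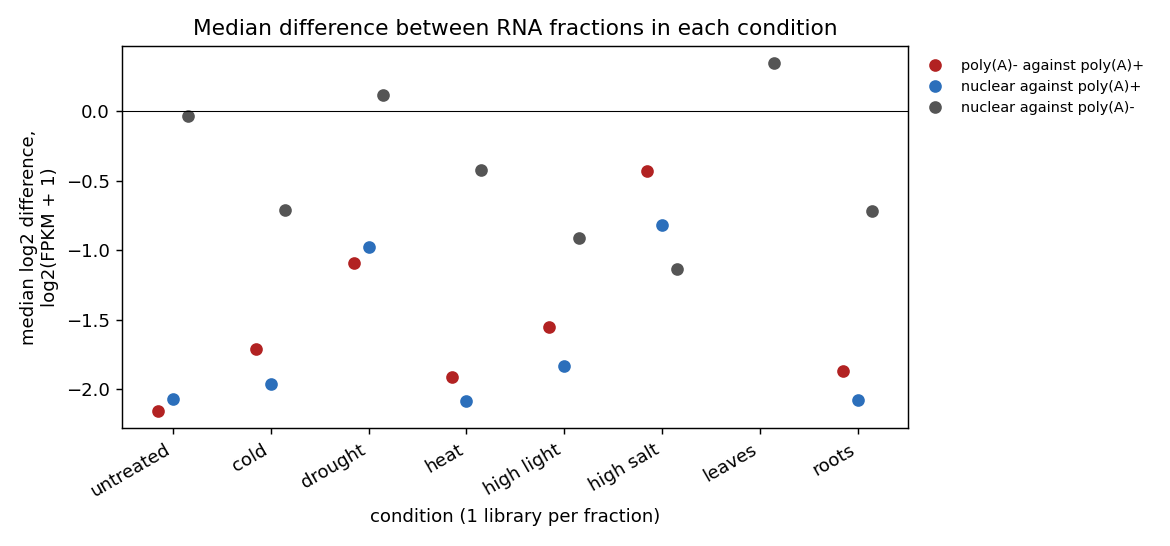
Median log2 difference between 2 RNA fractions over the genes tested, for each condition on the x axis; each point compares 1 library with 1 library. The difference between poly(A)- and poly(A)+ RNA lies near -2.16 in untreated seedlings and near -0.43 in high salt.

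Nuclear RNA had lower values than poly(A)+ RNA for most lncRNAs. Nuclear RNA was labelled as total RNA, and poly(A)+ and poly(A)- RNA as whole cell RNA. Comparisons of nuclear RNA with either therefore do not part location from poly(A) selection. Of 2786 genes tested over 7 conditions, 2206 were lower in nuclear RNA, of them 789 RAP and 1404 XLOC loci, and 35 were higher. The same sign in all 7 conditions was found for 1987 of the lower genes and 13 of the higher ones, and for none of the 11 higher EPlOSAG genes. XLOC_051819 on chromosome 4 (145577 to 145818, + strand) was the leading gene higher in nuclear RNA, with 68.9 ± 52.5 against 1.42 ± 1.72 FPKM (SD, n = 7 conditions). Its log2 difference was 4.66 ± 0.42 (SE, limma adjusted p = 1.12e-10). The most abundant gene of this set, XLOC_048089 on chromosome 3 (11539610 to 11540373, - strand), averaged 2358 ± 1304 in nuclear and 503 ± 432 FPKM in poly(A)+ RNA (limma adjusted p = 1.89e-05). Another listed locus covers the same interval on the opposite strand. Among 58 single-exon XLOC pairs of this kind, reads were equal in 4 of 435 long RNA values of at least 40 reads and within counting error of equal in 126, so the strands were not counted as 1, and how far they share reads was not measured. At the other end, XLOC_020883 on chromosome 11 (26510881 to 26511349, + strand) averaged 2.38 ± 0.81 in nuclear and 245 ± 70.7 FPKM in poly(A)+ RNA, a log2 difference of -6.17 ± 0.39 (limma adjusted p = 1.65e-12). XLOC_069307 on chromosome 6 (7591464 to 7592153, + strand) averaged 0.409 ± 0.27 against 80.8 ± 57.2 FPKM (limma adjusted p = 2.37e-12). Relative to each library's median, 534 genes were lower and 286 higher.

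Nuclear and poly(A)- RNA were closer to each other. Of 959 genes tested over 8 conditions, 161 were lower in nuclear RNA and 9 higher, with the same sign in all 8 conditions for 65 and 5 of them. XLOC_007631 on chromosome 1 (14567147 to 14567432, - strand) was higher in nuclear RNA in 8 of 8 conditions, with 3.16 ± 2.38 against 0.0963 ± 0.11 FPKM (SD, n = 8 conditions). Its log2 difference was 1.66 ± 0.28 (SE, limma adjusted p = 2.92e-06). XLOC_006327, also on chromosome 1 (4481099 to 4483367, - strand), averaged 2.27 ± 1.42 against 0.192 ± 0.17 FPKM (limma adjusted p = 3.98e-05). Lower in nuclear RNA were XLOC_020424 on chromosome 11 (22518806 to 22519203, + strand), with 2.24 ± 3.41 against 58.9 ± 52.0 FPKM, and XLOC_072070 on chromosome 6 (450463 to 450918, - strand), with 1.39 ± 2.13 against 35.5 ± 25.7 FPKM. Both had a limma adjusted p of 1.83e-07. Relative to each library's median, 73 genes were lower and 38 higher. Without a filter on low values no gene passed the threshold in limma, and 933 genes had an unadjusted p under 0.05, of which 162 were lower and 9 higher by 2-fold.

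The stress comparisons asked which lncRNAs differ between stressed and untreated seedlings. As deposited, the number of lncRNAs past the size rule in poly(A)+ libraries was lowest in cold (190 higher, 476 lower) and high light (197 and 558), larger in heat (424 and 541), and largest in drought (216 and 1556) and high salt (125 and 1828). In poly(A)- libraries nearly all were higher: 244 against 9 in cold, 152 against 10 in heat, 409 against 5 in high light and 619 against 4 in high salt, with drought the exception at 73 higher and 91 lower. In nuclear libraries the number ranged from 35 lncRNAs in all in high light to 144 in heat. These counts include shifts of whole libraries. All 5 stresses shared 1 untreated library per fraction. Untreated roots against the same poly(A)- library gave 437 higher and 104 lower, with a median log2 difference of 0.99. A low untreated poly(A)- library therefore cannot be told apart from a rise under stress. The median log2 difference was -0.14, -1.02, -0.02, -0.19 and -1.17 in cold, drought, heat, high light and high salt for poly(A)+ RNA, and 0.80, -0.11, 0.67, 0.96 and 1.08 in the same order for poly(A)- RNA.

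Relative to the median of each comparison, the poly(A)+ counts were 274 higher and 361 lower in cold, 609 and 421 in drought, 441 and 531 in heat, 300 and 400 in high light, and 327 and 354 in high salt, so that high salt no longer gave more than heat or high light. The poly(A)- counts were 33 and 43 in cold, 86 and 85 in drought, 25 and 41 in heat, 45 and 13 in high light, and 76 and 35 in high salt. The nuclear counts were 20 and 26, 36 and 19, 101 and 25, 20 and 14, and 26 and 14 in the same order, after median log2 differences of -0.25, -0.22, -0.32, -0.20 and -0.23.

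**Figure D2:**
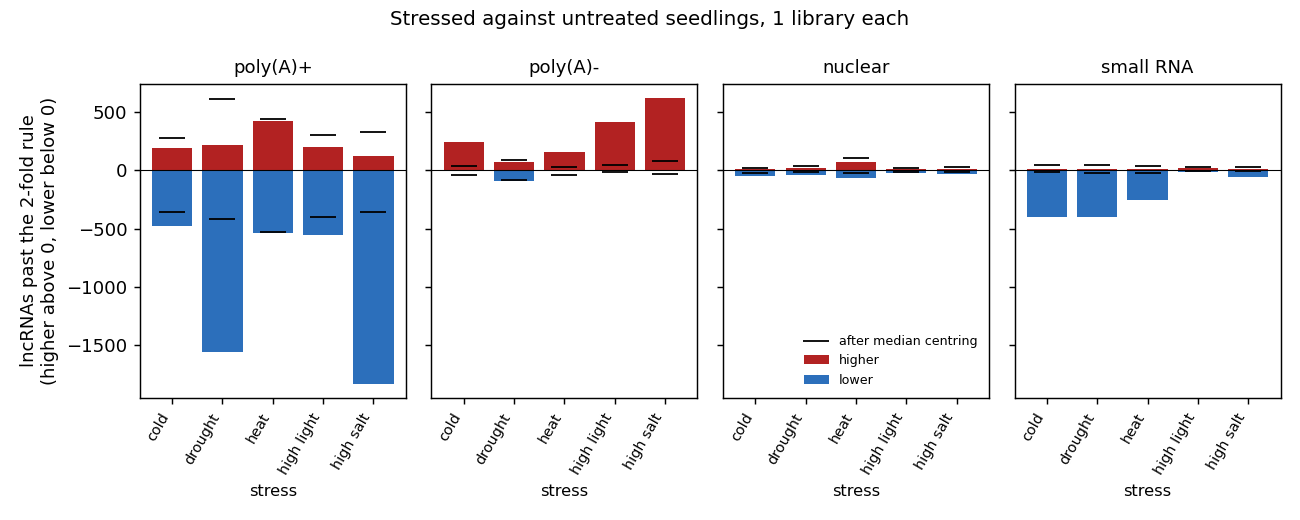
Number of lncRNAs past the 2-fold rule in each stress against untreated seedlings, with higher ones above 0 and lower ones below 0, for the 4 RNA fractions; black dashes give the counts after median centring. In high salt 1828 lncRNAs were lower in poly(A)+ RNA as deposited and 354 after centring.

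Few loci passed in the same direction in poly(A)+, poly(A)- and nuclear RNA together. Those named here also passed after centring, but the counts depended on the rule. Fractions of 1 condition are not replicates and may share RNA, so an overlap above that of independent lists is no separate support. In drought, 3 loci were higher and 12 lower in all 3 fractions, where independent lists would share 0.31 and 1.2 of the 185 loci at 1 FPKM in every fraction. After centring 8 were higher and 8 lower, and with a 4-fold rule 0 and 1. XLOC_067313, a 401 nt locus on chromosome 5 (26927841 to 26928242, - strand), stood at 8474 FPKM in drought (95% Poisson interval 8437 to 8511) and 7.57 (6.61 to 8.62) in untreated seedlings in poly(A)+ RNA. It took 14% of all listed reads of the drought poly(A)+ library. In poly(A)- RNA it had 207 FPKM (202 to 213) against 0.0617 (0.00748 to 0.223), and in nuclear RNA 2.51 (1.86 to 3.31) against a listed 0, for which 3 reads would be 0.152. In high salt it was the single locus higher in all 3 fractions, with 49.1 FPKM (46.4 to 51.9) in poly(A)+, 7.60 (6.77 to 8.50) in poly(A)- and 1.55 (1.10 to 2.12) in nuclear RNA. Independent lists would share 0.76 of 343 there, and the count was 3 higher and 1 lower after centring and 0 with a 4-fold rule. XLOC_077010 on chromosome 7 (4574157 to 4575078, + strand) was 4.19, 5.55 and 3.98 times as high in drought as in untreated seedlings in the 3 fractions. Of the lower loci, OS12G0115050 on chromosome 12 (733810 to 734096, + strand) had 11.1 FPKM (9.57 to 12.8) in drought and 177 (171 to 183) in untreated seedlings in poly(A)+ RNA, and 0.231 (0.063 to 0.592) against 39.9 (37.3 to 42.5) in poly(A)- RNA. OS03G0781501 on chromosome 3 (32398403 to 32399832, - strand) had 4.00 FPKM (3.23 to 4.90) against 57.6 (54.9 to 60.4) in poly(A)+ RNA.

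Heat gave 8 loci higher in all 3 fractions, where independent lists would share 2.4 of 251, and none lower. After centring 5 were higher and 2 lower, and with a 4-fold rule 2 and 0. The leading ones were neighbours on the + strand of chromosome 4. XLOC_053383 (16814257 to 16815627) had 23.2 FPKM (22.3 to 24.2) in heat and 0.470 (0.347 to 0.624) in untreated seedlings in poly(A)+ RNA, 18.4 (17.4 to 19.4) against a listed 0 in poly(A)- RNA, and 14.5 (13.6 to 15.4) against 0.237 (0.136 to 0.386) in nuclear RNA. XLOC_053384 (16817678 to 16817903) had 20.6 FPKM (18.5 to 22.8) against 0.298 (0.0969 to 0.696) in poly(A)+ RNA, and 11.1 and 13.8 FPKM against a listed 0 in the other 2 fractions. A further pair of the 8 loci were neighbours on the - strand of chromosome 2, between 9020909 and 9022874. Their nuclear levels in heat were 9.88 FPKM (8.62 to 11.3) and 3.28 FPKM (2.82 to 3.80), both from a listed 0.

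Cold gave 1 locus higher and 4 lower in all 3 fractions, where independent lists would share 0.34 and 0.07 of 293. After centring the counts were 2 and 4, and with a 4-fold rule 0 and 0. XLOC_093772, a 4906 nt locus on chromosome 9 (20884841 to 20889839, + strand), had 59.5 FPKM (58.8 to 60.2) in cold and 12.2 (11.8 to 12.5) in untreated seedlings in poly(A)+ RNA. The ratios were 23.4 in poly(A)- and 7.24 in nuclear RNA. XLOC_053058 on chromosome 4 (13465756 to 13466868, + strand) was lower in cold, with 0.342 FPKM (0.243 to 0.468) against 50.7 (49.2 to 52.2) in poly(A)+ RNA, 0.0682 (0.0222 to 0.159) against 2.40 (2.09 to 2.75) in poly(A)- RNA and 0.0153 (0.000388 to 0.0853) against 1.76 (1.42 to 2.14) in nuclear RNA. OS03G0285850 on chromosome 3 (9849590 to 9850194, + strand) had 0.828 FPKM (0.491 to 1.31) against 16.7 (14.9 to 18.7) in nuclear RNA. In high light, XLOC_053058 was the single locus past the rule in all 3 fractions, with 1.71 FPKM (1.38 to 2.08) in poly(A)+ RNA, and 0.266 (0.174 to 0.390) and 0.129 (0.0558 to 0.254) in poly(A)- and nuclear RNA. Independent lists would share 0.032 of 293 there, and the count was 1 higher and 2 lower after centring and 0 with a 4-fold rule. In heat its poly(A)+ level was 0.141 (0.0727 to 0.246) and its poly(A)- level 2.81 (2.39 to 3.29). None of these differences has a replicate check.

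**Figure D3:**
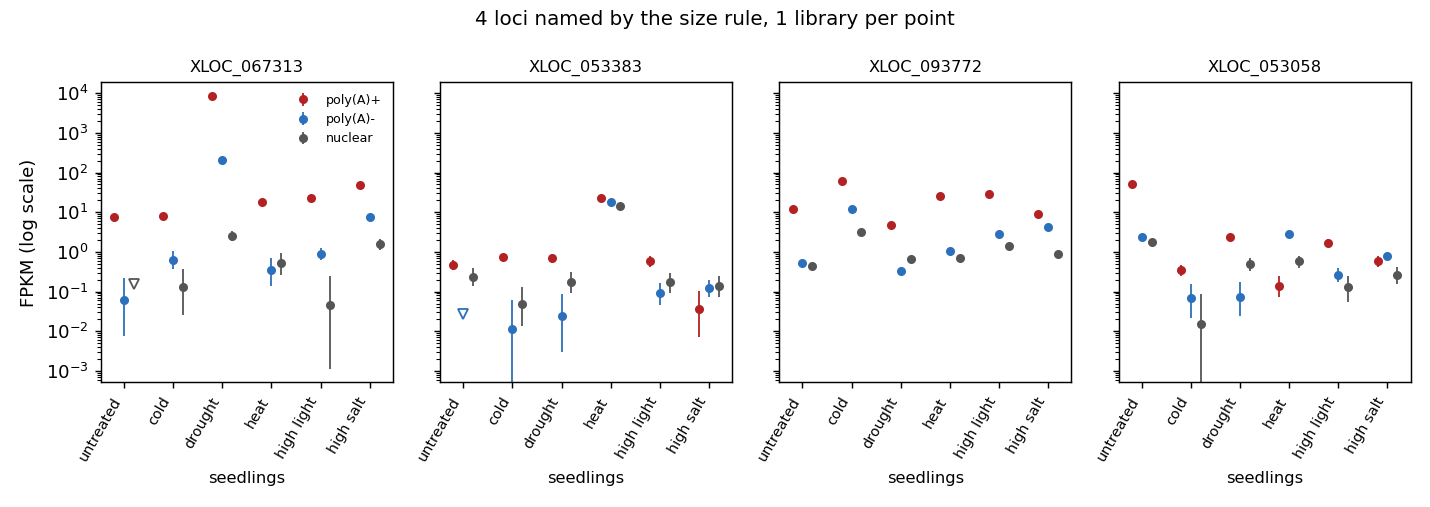
FPKM on a log axis of 4 loci in the 6 seedling conditions, with 1 library per point, exact 95% Poisson intervals as bars and open triangles at the limit of 3 reads where a locus was listed at 0. XLOC_067313 reached 8474 FPKM in drought poly(A)+ RNA, XLOC_053383 was high in heat in all 3 fractions, XLOC_093772 was highest in cold, and XLOC_053058 was highest, at 50.7 FPKM, in untreated poly(A)+ RNA.

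Small RNA values were mostly lower in cold (12 higher, 399 lower), drought (10 and 402) and heat (9 and 253), where EPlOSAG loci made up 312, 298 and 199 of the lower lncRNAs. High salt gave 7 higher and 58 lower, and high light 18 of each. All stresses shared the same untreated library, which had more loci at 1 FPKM (833 annotated, 255 XLOC) than any other small RNA library. Such loci numbered 307 and 130 in cold, 294 and 114 in drought, and 401 and 162 in heat. Untreated roots had 361 and 158, untreated panicles 219 and 125, and untreated leaves 661 and 180. A high untreated small RNA library therefore cannot be told apart from a fall under stress. The median log2 differences were -0.85 in cold, -0.87 in drought, -0.65 in heat, -0.39 in high salt and -0.18 in high light. Relative to them, 41 lncRNAs were higher and 14 lower in cold, 42 and 25 in drought, 33 and 24 in heat, 29 and 9 in high salt, and 29 and 7 in high light.

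Counts of higher and lower lncRNAs in roots against leaves went opposite ways in poly(A)- and nuclear RNA as deposited, and depended on the reference. In poly(A)- RNA 365 lncRNAs were higher and 149 lower in roots, and in nuclear RNA 14 were higher and 402 lower, with median log2 differences of 0.72 and -0.96. Relative to these medians, 83 were higher and 227 lower in poly(A)- RNA, and 40 and 88 in nuclear RNA. The nuclear library of leaves stood apart, with 310 annotated and 532 XLOC loci at 1 FPKM against 81 to 139 and 116 to 243 in the other undisputed nuclear libraries. Its rank correlation was 0.843 with poly(A)+ and 0.839 with nuclear libraries. Against untreated seedlings, roots had 437 higher and 104 lower in poly(A)- RNA and 45 and 144 in nuclear RNA. Relative to the medians these were 92 and 152 in poly(A)- RNA, but 90 and 33 in nuclear RNA, the opposite order to that against leaves. In both fractions together 11 loci were higher and 74 lower in roots, where independent lists would share 3.7 and 39 of 507. After centring the counts were 11 and 54, of which 8 and 47 were shared with the first ones. Against seedlings, a reference added here after the data were seen, 29 loci were higher and 43 lower in both fractions, of which 8 and 21 were shared with those against leaves. With a 4-fold rule against leaves the counts were 2 and 25. XLOC_030490 on chromosome 12 (22581426 to 22581943, - strand) had 56.0 FPKM (53.4 to 58.7) in roots against a listed 0 in leaves in poly(A)- RNA, and 2.31 (1.78 to 2.96) against 0.387 in nuclear RNA, where untreated seedlings had 4.01. XLOC_082548 on chromosome 7 (22421102 to 22421325, - strand) had 23 FPKM (20.4 to 26) against 0.662 in nuclear RNA. Lower in roots were XLOC_043227 on chromosome 3 (11539610 to 11540373, + strand), with 29.7 FPKM (28.1 to 31.3) against 3912 in poly(A)- RNA, and XLOC_005753 on chromosome 1 (528696 to 528964, - strand), with 5.20 (4.15 to 6.45) against 617. XLOC_048089, on the same interval as XLOC_043227 and the opposite strand, had 34.4 against 4508 FPKM. Of the 74 lower loci, 4 had such a partner among them. In small RNA 21 lncRNAs were higher and 133 lower in roots than in leaves, and 37 higher and 281 lower in panicles. Relative to median log2 differences of -0.26 and -0.80, these counts were 58 and 81 for roots and 86 and 39 for panicles. The long RNA of panicles and the poly(A)+ RNA of leaves were left out of these counts, because their column headings disagreed between the lists.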

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

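The tests of the column headings, the exchanges of fractions, and the comparisons and ratios of the same loci between libraries were chosen only after the results were seen. The other tests on the drought and high salt libraries were written down before.

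Signal was present in the 4 columns that the main comparisons did not use. In the annotated list, lncRNAs of at least 1 FPKM numbered 958 in the column headed poly(A)+ of leaves, 1039 in poly(A)+ of panicles, 102 in poly(A)- of panicles and 298 in nuclear RNA of panicles. In the XLOC list the numbers under the same headings were 322, 1971, 629 and 2528. By their depth, the library of 106.9 M reads stood under poly(A)+ of leaves in the annotated list and under poly(A)+ of panicles in the XLOC list. The library of 113.5 M stood under poly(A)+ and nuclear RNA of panicles in that order, that of 132.4 M under poly(A)- of panicles and poly(A)+ of leaves, and that of 104.4 M under nuclear and poly(A)- RNA of panicles.

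Headings displaced in one of the lists may account for this. Each library was compared by rank correlation over all lncRNAs with the undisputed libraries of each fraction, and 21 of 23 undisputed libraries were closest to their own fraction, the exceptions being poly(A)- RNA of drought (0.718, against 0.721 with nuclear RNA) and nuclear RNA of leaves (0.839, against 0.843 with poly(A)+ RNA). Headings displaced in the XLOC list remain open, since 4 of 4 annotated headings named the closest fraction. Displaced headings in the annotated list are argued against, since 1 of 4 XLOC headings did so. The test reads fractions and not tissues, and no biological explanation was tested.

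In poly(A)+ RNA, values were lower in drought and high salt than in untreated seedlings for most lncRNAs, by a median log2 of -1.51 and -1.87 among 2193 and 2164 loci rich in poly(A)+ RNA in roots. A single scale factor as the sole cause is argued against. The lncRNAs rich in poly(A)- RNA in roots changed by 3.08 (95% bootstrap interval 2.40 to 3.67) and 4.42 (3.98 to 5.14) more. The 2 sets also parted in cold, heat and high light, with poly(A)- rich medians of 1.49, 1.22 and 1.61. The poly(A)+ rich medians there were -0.15, -0.10 and -0.15, so a scale factor as part of the fall stays open. Lower levels in nuclei are argued against for the 455 and 526 poly(A)+ rich loci measured in both libraries. Nuclear medians of these loci were -0.24 (-0.33 to -0.14) and -0.17 (-0.25 to -0.07) against -1.43 and -1.75 in poly(A)+ RNA. For loci chosen by untreated reads alone they were -0.51 against -1.62 and -0.45 against -1.84. The other loci had too few nuclear reads to tell. Carry-over of poly(A)- RNA predicted a rise of the poly(A)- rich set in the poly(A)+ library, which was met in drought with 1.57 (0.90 to 2.19) and in high salt with 2.55 (2.07 to 3.24), but also in cold, heat and high light with 1.49, 1.22 and 1.61, so this test does not part them. Beyond the change of the same loci in the poly(A)- library, the rise was 1.25 (0.68 to 2.07) for 65 loci in high salt and 0.88 (0.27 to 1.32) for 56 in drought, against 0.44, 0.34 and 0.24 in cold, heat and high light (1.27, 0.43, 0.22, 0.33 and 0.29 in that order for the 44 loci chosen by untreated reads alone), so a larger share of poly(A)- RNA may contribute in high salt and cannot be told apart in drought, although the set has 155 loci, with medians in the poly(A)- libraries of 2.14 and -0.09 where measured. Dilution alone would need carried shares of 0.648 in drought and 0.727 in high salt, above the median poly(A)+ to poly(A)- ratios of 0.282 and 0.13, but this assumes the profile of the poly(A)- library, which 6 loci of 1811 nt left in high salt (888 against 602 FPKM), and loss of poly(A) tails stays open and untested with 1 column each.

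In poly(A)- RNA under high salt, poly(A)+ rich lncRNAs were higher by a median log2 of 2.26 and poly(A)- rich ones by 2.14. Poly(A)+ RNA left in the poly(A)- library would raise the first set more, and the difference was 0.12 (-0.05 to 0.42). The interval reaches past the limit of 0.3 set for the test, so such a remainder cannot be told apart from a rise of both sets. Nor was the rise confined to high salt. Poly(A)- rich lncRNAs were higher by 1.44, 1.28 and 1.65 in poly(A)- RNA of cold, heat and high light, but not of drought (-0.09). All these comparisons share the untreated poly(A)- library, so a low library there cannot be told apart either.

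Exchanging the fractions within conditions asked whether arbitrary labels of the fractions could give as many differing lncRNAs. For poly(A)- against poly(A)+ RNA 1 of 64 arrangements, the real one, reached 2251, and the highest other gave 2089. For nuclear against poly(A)+ RNA it was 1 of 64, with 2241 and 2021, and for nuclear against poly(A)- RNA 1 of 100 drawn, with 170 and 101. Arbitrary labels are argued against at 0.05 for all 3 numbers. Both comparisons with poly(A)+ RNA had negative median differences in all 7 conditions, so any exchange mixed opposite shifts. The exchanges therefore read mainly the shift between libraries there, and not single lncRNAs. After median centring the real numbers were 717, 820 and 111 in the same order, and the highest others 178, 91 and 0.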

How the results depend on the processing

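The 9-condition fits, the comparison with RAP loci alone and seedlings as the reference for roots over both fractions were chosen only after the data were seen; all other alternatives were planned. Of 368 alternatives, 178 kept the direction and the side of the threshold, or a count within 1.5 times, among them 3 for median exon number, which could not differ. Size-rule counts with no minimum value, also among the 178, could not differ either. A 2-fold difference on log2(FPKM + 1) already needs at least 1 FPKM in one of the columns. Where a cause is not named below, the cause was not tested. Fractions were paired by condition in every fraction test. No paired analysis was possible because, for the replicate numbers of drought, the 2 libraries of a fraction share 1 column, so fits without drought replicate 1 or 2 were not run. Also not run were the position against protein-coding genes, the lists of neighbouring genes, the authors' own comparison columns, and leaves as the control in poly(A)+ RNA. Depth limits the low loci most: 3 reads in the shallowest long RNA library are 0.271 FPKM for XLOC_053384, a locus of 225 nt.

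Leaving out each condition gave 106 to 128 higher and 1983 to 2299 lower lncRNAs for poly(A)- against poly(A)+ RNA, 24 to 40 and 2095 to 2329 for nuclear against poly(A)+ RNA, and 6 to 13 and 121 to 211 for nuclear against poly(A)- RNA. Median centring gave 245 and 472, 286 and 534, and 38 and 73 in the same order. For nuclear against poly(A)+ RNA the higher lncRNAs were 57 with a pseudocount of 0.1, 54 with 0.01, 23 with no filter and 15 in 9 conditions under the XLOC headings. For nuclear against poly(A)- RNA they were 37 (300 lower) with 0.1, 29 with 0.01, 0 (0 lower) in limma with no filter, where 933 had an unadjusted p under 0.05, of which 9 were higher and 162 lower by 2-fold, and 14 in seedlings alone. With no filter, the prior degrees of freedom fell to 0.952 for this comparison. Its 9-condition fits gave 3 higher and 73 lower with columns as headed, 15 higher under the annotated headings, and 3 higher and 43 lower under the XLOC headings.

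Numbers past the size rule follow in the order cold, drought, heat, high light and high salt. A 4-fold rule, stricter by construction, gave 97, 510, 168, 92 and 510 in poly(A)+, 19, 43, 15, 44 and 86 in poly(A)-, 4, 3, 28, 2 and 1 in nuclear and 11, 17, 8, 2 and 3 in small RNA. Roots against leaves then gave 96, 89 and 31 in poly(A)-, nuclear and small RNA, and panicles 29 in small RNA. A minimum of 5 FPKM, which tests fewer loci, gave 380, 940, 558, 426 and 1035, then 83, 61, 66, 169 and 186, then 12, 17, 58, 11 and 16, and 193, 195, 145, 21 and 26 in the 4 fractions. Roots then gave 156, 113 and 47, and panicles 95.

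A pseudocount of 0.1 gave 1138 in cold, 1497 in heat and 1225 in high light in poly(A)+ RNA. In all 5 stresses it gave 548, 266, 350, 801 and 956 in poly(A)-, 170, 160, 279, 120 and 151 in nuclear and 850, 896, 612, 168 and 294 in small RNA. Roots gave 716 in nuclear and 410 in small RNA, and panicles 681. With 0.01 the numbers were 1180, 1552 and 1268, then 559, 273, 373, 812 and 975, then 184, 186, 292, 132 and 161, and 875, 924, 647, 197 and 325. Roots gave 732 and 434, and panicles 700.

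Median centring gave 1030 in drought and 681 in high salt in poly(A)+ RNA, and 76, 66, 58 and 111 in cold, heat, high light and high salt in poly(A)- RNA. In small RNA it gave 55, 67, 57 and 38 in cold, drought, heat and high salt. Roots gave 310 in poly(A)- and 128 in nuclear RNA, and panicles 125. Leaves as the control gave 273 in drought and 317 in heat in poly(A)- RNA, 392, 425, 476, 401 and 450 in nuclear RNA, and 130, 138, 88 and 105 in cold, drought, heat and high light in small RNA. With seedlings as the reference, roots gave 189 in nuclear and 272 in small RNA, and panicles 602. Of the 74 counts over all fractions under these alternatives, 33 stayed within 1.5 times, including those with no minimum value, which could not differ. With a minimum of 5 FPKM they were 2 higher and 2 lower in drought, 5 higher in heat, 0 in cold, high light and high salt, and 1 higher and 25 lower in roots against leaves. With seedlings as the reference for roots they were 29 and 43.

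Between the lists, XLOC minus annotated, means gave -0.581 exons (adjusted permutation p = 1e-05, the smallest possible) and 0.16 for the log2 difference of poly(A)- from poly(A)+ RNA (0.0005). Matched on level, length reversed to -9 nt (0.63) and that log2 difference to -0.0748 (0.241). The small RNA level then differed by -0.00343 (0.241), and the nuclear to poly(A)+ difference was 0.0929 (0.241). Against RAP loci alone, length reversed to -72 nt (3e-05), the long RNA level differed by 0.0284 (0.182) and the small RNA level by -2.37e-05 (adjusted permutation p = 1). Among transcripts of at least 300 nt the odds of the poly(A)+ class reversed from 2.54 to 0.805 (Fisher's exact test, adjusted p = 0.00082), and those of the cytosolic class went from 3.78 to 1.14 (0.064). This alternative leaves out short loci by construction.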

Other observations

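Tests and values in this part were all chosen after the data were seen.

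In small RNA, a few loci stood far from the rest. XLOC_069398 on chromosome 6 (8367050 to 8367434, + strand) had 101 FPKM in heat and 91.2 in high salt, against 0.46 in untreated seedlings. EPlOSAG00000051181 on chromosome 6 (27674745 to 27674951, + strand) had 904 FPKM in drought against 49.7. EPlOSAG00000001961 on chromosome 1 (42923735 to 42923973, - strand) was at 28.8 FPKM in untreated seedlings and lower in all 5 stresses, at 0.171 in cold, 0.049 in drought, 4.43 in heat, 0.0907 in high light and 0.444 in high salt. All 5 ratios share 1 untreated library, so a high value there would give the same order.

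A group of 6 EPlOSAG loci of 1811 nt, whose highest value was within 1.2 times the lowest in 18 of 32 libraries, were among the loci of most reads. EPlOSAG00000008517 to EPlOSAG00000008521 lay on chromosome 9, between 3625 and 37148, and EPlOSAG00000008516 on chromosome 2. Whether these 6 are lncRNAs was not tested, since no annotation of this build was used. Their median was 87.7 FPKM in poly(A)+ RNA of untreated seedlings, 107 in cold, 97 in drought, 307 in heat, 324 in high light and 888 in high salt. In poly(A)- RNA the medians were 710, 798, 659, 1742, 830 and 602 in the same order, and in small RNA 1009, 4648, 1894, 1326, 2492 and 1051. In drought the lowest of the 6 stood apart, at 35.3 FPKM in poly(A)+ and 194 in poly(A)- RNA. The other 12 libraries past this limit were nuclear or small RNA, such as nuclear RNA in cold with 437 to 611 FPKM. How reads that map to several places were counted is not given in the sources used here, so the 6 may not be separate measurements. They entered the tests and counts as separate loci. EPlOSAG00000008517 to EPlOSAG00000008521, with limma log2 differences between -1.067 and -1.061, each counted among the 161 genes lower in nuclear than in poly(A)- RNA.

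The authors' poly(A) classes were compared with a 4-fold rule on the highest poly(A)+ and poly(A)- value of each lncRNA. The class matched for 2196 of 2221 annotated lncRNAs (98.9%) and, with columns as headed, for 3448 of 3480 XLOC lncRNAs (99.1%). With the XLOC values placed under the annotated headings, 2762 matched (79.4%) and 718 differed. The authors may have made the classes from the columns as headed, so this match does not tell which headings are right.

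The disputed columns set the tissue counts. For poly(A)+ RNA of roots against leaves, 414 lncRNAs were higher and 630 lower under the annotated headings, 1773 and 308 with columns as headed, and 2492 and 173 under the XLOC headings. For nuclear RNA of panicles against leaves the counts were 134 and 120, 2276 and 133, and 3160 and 118 in the same order.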
